A study of Mus musculus with 48 samples.

How the data were processed

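Gene expression was measured in mouse liver after administration of 1 of 3 modified gapmer antisense oligonucleotides directed against Scarb1, named LX-A1656, LX-A2003 and LX-A3928 in the labels, or of PBS as the vehicle. A gapmer is a short DNA-like strand with chemically modified ends that pairs with its target transcript and directs RNase H to cleave it. Livers were sampled at 24 h, 72 h and 168 h, which the series describes as days 1, 3 and 7 after the first administration. Each of the 12 combinations of treatment and time had 4 replicates, 48 libraries in all. The labels do not say whether the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. Doses, oligonucleotide sequences, dosing after the first administration, sex, strain, hours of tissue collection and sequencing runs are not given in the sources used here.

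Per the labels, tissue was homogenized with beads in TriPure reagent, total RNA was extracted, and libraries were made with the Ion AmpliSeq Transcriptome kit for mouse genes. This kit amplifies a designed fragment of each gene by PCR, so a value reports on that fragment alone and not on the rest of the transcript. The position of the Scarb1 fragment relative to the oligonucleotide sites is not given in the sources used here, nor are the aligner, the counting tool, the genome build, the strand or any filter. The deposited values are raw read counts per gene target. They are whole numbers, and the column totals ranged from 8140065 to 17191129 with a median of 10659453. All 48 sample columns were used, and each joined to its group through the library name in the labels.

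The table listed 23930 genes. Genes were kept for testing by the edgeR function filterByExpr applied to the 12 groups, which left 12672 genes holding at least 99.891% of the counts of every library. Libraries were scaled with TMM factors. One model with 12 group means was fitted to all 48 libraries with the edgeR robust quasi-likelihood method and its F test, with 36 residual degrees of freedom, a median prior of 9.045 degrees of freedom and a common biological coefficient of variation of 0.2114. All groups therefore share the estimate of the dispersion. P-values were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, and a gene with an adjusted p under 0.05 is called changed. A second count required an absolute log2 fold change of at least 1. Fold changes are log2 values with a standard error, computed as the absolute log2 fold change divided by the square root of F. Levels are read counts scaled to library size with TMM factors (CPM), given as mean and SD of 4 libraries. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom from 5.79 to 219.8 between pairs, so no library was a copy of another.

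Where a group had 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the whole group. Where it had 1 to 3 counts, the ratio of the groups is given with its 95% interval for counts (exact Clopper-Pearson), and no fitted fold is printed. These intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. For paralogs and multigene families, such as the major urinary proteins, sulfotransferases, carboxylesterases, Cyp2 and glutathione transferase genes, reads could not be checked for assignment between members.

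The 23 comparisons were each oligonucleotide against PBS at the same time, each pair of oligonucleotides at the same time, the difference between the 168 h and 24 h effects of each oligonucleotide against PBS (an interaction), and PBS at 72 h and at 168 h against PBS at 24 h. The comparisons, tests, gene lists and rule for naming genes were fixed before the data were examined. For each oligonucleotide against PBS, the named genes are Scarb1; the 5 highest and 5 lowest log2 fold changes among changed genes with a mean of at least 10 CPM in 1 of the groups and all 4 treated libraries beyond all 4 PBS libraries; and up to 4 members with the smallest p from each list with a changed member. For the other comparisons they are Scarb1 and up to 3 highest and 3 lowest by the same criteria, without the separation of libraries for interactions.

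The 30 gene lists comprised 18 pathways and 12 cell type marker sets. The pathway lists were sterol synthesis, cholesterol and HDL transport, bile acid synthesis and transport, fatty acid synthesis, fatty acid oxidation, p53 targets, endoplasmic reticulum (ER) stress and integrated stress response, NRF2 targets, interferon response, inflammatory cytokines and NF-kB targets, acute phase response, cell cycle, xenobiotic metabolism, hepatocyte function, injury and immediate early genes, oligonucleotide uptake and RNase H, lysosome, and circadian clock. The marker lists were for Kupffer cells, monocytes and recruited macrophages, neutrophils, T cells, NK cells, B and plasma cells, sinusoidal endothelial cells, stellate cells and fibroblasts, cholangiocytes, erythroid cells, pancreatic acinar cells and adipocytes. Together they held 485 genes. Of these, 4 stood in a second list: Ephx1, Stab2, Gpnmb and Pltp. PBS livers expressed 355 of them at a mean of at least 1 CPM. Lists were tested with limma camera, two-sided, with a preset inter-gene correlation of 0.01, adjusted over the 30 lists within a comparison. Camera compares a list with all other genes, so it is little affected by the scale of a library. Each test was repeated with the correlation estimated from the residuals and with fry, which tests whether a list's genes move one way. Members past the threshold were counted over all genes tested and also adjusted over the list alone.

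The comparisons of different oligonucleotides with PBS at 1 time share the same PBS libraries, which makes their fold changes correlate without any common effect. For each pair, the covariance of the fold changes across genes and the overlap of calls were set beside 20 simulations with unchanged groups, beside the overlap of independent calls, and beside 6 assignments in which each oligonucleotide was compared with 2 of the PBS libraries.

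The pipeline was tested on simulated data built on the LX-A1656 and PBS counts at 24 h. Of the genes given a 1.5-fold change 10 of 66 were called, of those given a 2-fold change 38 of 67, and of those given a 4-fold change 58 of 66, while 3 of 111 calls were genes left unchanged. The sterol synthesis list raised 1.5-fold was called by camera, adjusted p = 2.99e-15, and with an estimated correlation, adjusted p = 2.62e-09. Camera called no other list there. Genes were drawn independently of each other, so these values do not test list calls that arise from correlation between genes.

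The alternatives tried were RLE factors, no low-count filter beyond 1 count, a replicate block, a block for 6 sets of 8 libraries defined by library number, fits of only the 8 or 16 libraries compared, DESeq2, and leaving out each library. Added after the data were seen were scaling by library totals alone, leaving out 6 libraries far from the mean of their group, leaving out 2 PBS libraries at 168 h, and a covariate for the mean level of 10 small nuclear and nucleolar RNA genes. Gene locations and spans were taken by symbol from the GENCODE M21 annotation of GRCm38, which may differ from the build the authors used. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9. Sequence matches of the oligonucleotides to other transcripts were not examined, since no sequences were available.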

Results

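Transcript levels were measured in 48 mouse liver libraries with a targeted amplicon kit that reads a fragment of each gene. There were 12 groups of 4 replicates: PBS and the gapmer oligonucleotides LX-A1656, LX-A2003 and LX-A3928, each at 24 h, 72 h and 168 h after first administration. Library totals ran from 8140065 to 17191129 counts, and 12672 genes were tested. Fold changes below are log2 values ± SE with 4 libraries per group, and adjusted p-values are from the edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment over the genes tested. Genes given as highest or lowest had all 4 libraries of a group beyond all 4 of the other. Counts of a list's genes are also given adjusted over the list alone where these differ by 2 or more. Members named because they moved against the rest of a list were chosen after their values were seen.

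The first principal component carried 56.4% of the variance. PBS groups had a mean of -49.5 ± 2.23 (SD) at 24 h, -51.7 ± 0.598 at 72 h and -46.4 ± 6.39 at 168 h on it. The LX-A1656 group stood at 50.3 ± 16.5 at 72 h and 120.2 ± 8.19 at 168 h, LX-A2003 at -21.8 ± 3.18 and 94.5 ± 7.87, and LX-A3928 at -29.6 ± 3.99 and 67.2 ± 13.3. The mean number of genes detected was 13830 in PBS livers at 168 h, and 16009.8, 15847.2 and 15710.8 with LX-A1656, LX-A2003 and LX-A3928.

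Scarb1, the target of the oligonucleotides and the gene for a receptor that takes up HDL cholesterol, lies on chromosome 5 from 125277087 to 125341094 (GRCm38, minus strand). Its level in PBS livers was 271.6 ± 24.2 CPM (SD, n = 4) at 24 h, 304.4 ± 9.01 at 72 h and 319.7 ± 78.8 at 168 h. At 24 h it was 10.6 ± 1.04 CPM with LX-A1656, 23.0 ± 7.80 with LX-A2003 and 48.1 ± 9.78 with LX-A3928, or 3.89%, 8.48% and 17.7% of PBS. At 72 h the means were 4.42 ± 1.23, 5.59 ± 1.45 and 7.83 ± 2.19 CPM, or 1.45%, 1.84% and 2.57% of PBS. At 168 h they were 16.3 ± 3.75, 12.5 ± 1.91 and 9.32 ± 3.11 CPM, or 5.10%, 3.91% and 2.92%. These levels describe the amplified fragment, whose position relative to the oligonucleotide sites is not known.

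**Figure D1:**
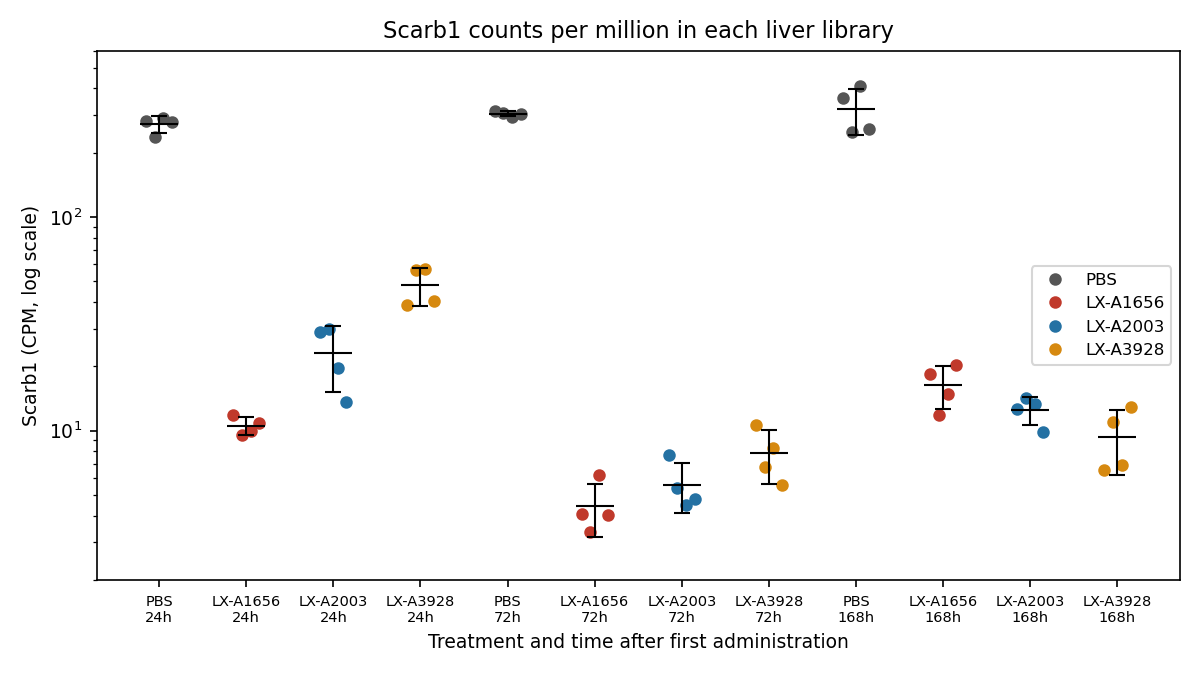
Scarb1 level in CPM on a log axis for PBS and each oligonucleotide at each time after first administration in h, with a point for each library and a horizontal line at the mean of 4 libraries with bars of 1 SD. PBS means lie between 271.6 and 319.7 CPM and all oligonucleotide means at or below 48.1 CPM.

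In LX-A1656 livers at 24 h, Scarb1 fell by 4.68 ± 0.248 against PBS (adjusted p = 6.63e-19). Bmf, which encodes a pro-apoptotic BH3-only protein, rose by 1.98 ± 0.427 (adjusted p = 0.00318). The lowest after Scarb1 were the mitochondrial carrier gene Slc25a21 at -3.12 ± 0.306 (adjusted p = 5.2e-10), Adam23 at -2.99 ± 0.229 (adjusted p = 2.01e-13), Naaladl2 at -2.86 ± 0.348 (adjusted p = 1.62e-07) and the endothelial receptor gene Kdr at -2.78 ± 0.204 (adjusted p = 5.64e-14). Slc25a21, Adam23, Naaladl2 and Kdr span 484.8, 150.4, 1346 and 45.6 kb of the genome, against a median of 24.3 kb for the genes tested. In sterol synthesis 4 of 19 genes rose, among them Insig1, Msmo1 and Fdft1, and 12 rose when adjusted over the list alone (camera adjusted p = 3.65e-12; adjusted p = 0.0455 with an estimated correlation). Of the 12 sinusoidal endothelial markers, Kdr, Stab2 (-2.21 ± 0.203) and Oit3 fell, and 5 fell when adjusted over the list alone (camera adjusted p = 1.55e-14; adjusted p = 4.86e-08 with an estimated correlation). Fatty acid oxidation genes were shifted upward (camera adjusted p = 0.00664; adjusted p = 0.541 with an estimated correlation), with Angptl4 and Cpt1a among the 3 genes called, and 3 also adjusted over the list alone. NRF2 targets (camera adjusted p = 0.0233; adjusted p = 0.341 with an estimated correlation) and the lysosome list (camera adjusted p = 0.0421; adjusted p = 0.508 with an estimated correlation) were also shifted upward, with Nqo1 and Ugdh, and Npc1, called. Adjusted over the list alone, 3 genes rose and 1 fell among NRF2 targets and 3 rose in the lysosome list. Among 16 clock genes Dbp and Cry2 rose while Cry1, Npas2 and Hlf fell, or 5 and 5 adjusted over the list alone, and the median was -0.0614, the mean 0.0878 and the test direction downward (camera adjusted p = 0.848). Hamp, the gene for the iron hormone hepcidin, fell by 2.54 ± 0.309 (adjusted p = 1.85e-07). In all, 363 genes were changed, 125 higher and 238 lower, of which 52 and 107 had an absolute log2 fold change of at least 1. Without PBS replicate 1 the count was 239, and with only the 8 libraries compared 803.

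With LX-A2003 at 24 h, Scarb1 fell by 3.56 ± 0.232 (adjusted p = 2.02e-15). The clock output gene Dbp rose by 4.13 ± 0.592 (adjusted p = 2.16e-05), from a PBS level of 1.16 ± 0.886 CPM, which itself was 16.5 ± 9.49 CPM in PBS livers at 72 h and 0.894 ± 0.360 at 168 h. Next were the hormone gene Fgf21 at 2.95 ± 0.678 (adjusted p = 0.00972) and Bmf at 2.13 ± 0.423 (adjusted p = 0.00187). The lowest after Scarb1 were the chloride channel family gene Clic3 at -2.39 ± 0.283 (adjusted p = 3.06e-07), Naaladl2 at -2.39 ± 0.330 (adjusted p = 8.27e-06) and Arfgap3 at -2.03 ± 0.248 (adjusted p = 5.62e-07). Among ER stress genes Chac1 (2.18 ± 0.371) and Fgf21 rose, while the chaperone genes Dnajb9 (-1.14 ± 0.20), Sdf2l1, Creld2 and Hyou1 fell (3 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.241), and the median was -0.126, the mean 0.0587 and the test direction downward. Of the clock genes Dbp, Nr1d2, Tef and Cry2 rose and Cry1, Hlf and Nfil3 fell, or 6 and 5 adjusted over the list alone, and the median was -0.0315, the mean 0.224 and the test direction upward (camera adjusted p = 0.797). The sterol synthesis list was shifted upward with no single gene passing (camera adjusted p = 0.0124; adjusted p = 0.606 with an estimated correlation). NRF2 targets, with Nqo1 called, lysosome genes, with Npc1 among those called, and neutrophil markers, with no call, all had a camera adjusted p = 0.0124 or 0.0204, and each had an adjusted p = 0.293 with an estimated correlation. Kdr (-0.96 ± 0.185) and Stab2 (adjusted p = 0.00105) fell among the endothelial markers (camera adjusted p = 0.146). In total 265 genes were changed, 119 higher and 146 lower, with 58 and 60 at an absolute log2 fold change of at least 1. The count was 135, 162 and 174 without PBS replicate 1, 2 or 4, and 145 and 149 without LX-A2003 replicate 3 or 4. Without LX-A2003 replicate 3 the majority turned, with 77 higher and 68 lower. With only the 8 libraries compared the count was 754.

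With LX-A3928 at 24 h, Scarb1 fell by 2.50 ± 0.220 (adjusted p = 9.97e-11). Dbp rose by 5.99 ± 0.600 (adjusted p = 7.31e-09), followed by the transcription factor genes Foxq1 at 3.69 ± 0.483 (adjusted p = 1.56e-06) and Myc at 3.10 ± 0.471 (adjusted p = 2.39e-05). Nr0b2, which encodes a repressor of bile acid synthesis, fell by 3.15 ± 0.380 (adjusted p = 2.53e-07), and the clock gene Npas2 was at -3.15 ± 0.341 (adjusted p = 1.35e-08) and Zbtb7c at -2.99 ± 0.300 (adjusted p = 4e-09). Of 16 clock genes 5 rose, Dbp, Per3, Tef, Nr1d2 and Cry2, and 4 fell, Arntl, Npas2, Nfil3 and Cry1, with 8 and 4 adjusted over the list alone (camera adjusted p = 0.168). The cholangiocyte marker Sox9 fell by 1.87 ± 0.249 (adjusted p = 1.56e-06), and its list had a camera adjusted p = 0.085. Myc, Junb and Gadd45a rose among injury genes, a list whose median was -0.167, mean 0.194 and test direction upward (camera adjusted p = 0.624). G6pc, for the last step of glucose release, fell by 1.77 ± 0.341 (adjusted p = 0.00096). Kdr (-0.91 ± 0.184) and Stab2 (-1.28 ± 0.193) fell among the endothelial markers (camera adjusted p = 0.168). Of the 30 lists, 0 had a camera adjusted p under 0.05 and 6 had an unadjusted p under 0.05, while fry, whose question is different, called 5. In total 413 genes were changed, 213 higher and 200 lower, with 86 and 82 at an absolute log2 fold change of at least 1. The count was 252 and 263 without PBS replicate 1 or 2, and 248 and 260 without LX-A3928 replicate 1 or 4. The majority of calls turned to lower genes without PBS replicate 1, 2 or 4 (115, 125 and 155 higher, 137, 138 and 163 lower), with library totals alone (152 higher, 186 lower), with DESeq2 (49.46% of 556 higher) and with only the 8 libraries compared (714 higher and 721 lower of 1435).

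At 72 h the comparison with PBS asked the same question on the third day. With LX-A1656, Scarb1 fell by 6.10 ± 0.267 (adjusted p = 4.41e-23). The epithelial keratin gene Krt5 had 0 counts in PBS livers and 1003 in treated ones, at least 250-fold higher, and the AP-1 subunit gene Fosl1, with 0 PBS counts, was at least 231-fold higher. The tight junction gene Cldn4 rose by 9.70 ± 0.527 (adjusted p = 1.59e-19). The lowest fold changes were those of Slc25a21 at -7.16 ± 0.434 (adjusted p = 2.4e-18), Fhit, a gene of 1612 kb, at -6.84 ± 0.527 (adjusted p = 5.89e-15), and the heparan sulfate proteoglycan gene Sdc2 at -6.48 ± 0.210 (adjusted p = 8.37e-28). In sterol synthesis 17 of 19 genes rose and Stard4 fell, with Sqle, the squalene epoxidase gene, at 7.23 ± 0.361 and Cyp51 at 3.18 ± 0.213 (camera adjusted p = 1.07e-13; adjusted p = 0.00868 with an estimated correlation). All 17 injury and immediate early genes rose, Tnfrsf12a by 5.15 ± 0.243 and Anxa2 by 4.44 ± 0.241 (camera adjusted p = 7.34e-22; adjusted p = 3.18e-06 with an estimated correlation). The interferon response rose in 19 of 22 genes, with the chemokine gene Cxcl10 at 5.41 ± 0.294 and Rsad2 at 5.02 ± 0.295 (camera adjusted p = 1.39e-19; adjusted p = 1.28e-05 with an estimated correlation). In the inflammatory list 14 of 15 genes rose, Ccl2 by 6.61 ± 0.452 (camera adjusted p = 2.78e-09; adjusted p = 4.97e-06 with an estimated correlation). Of 25 p53 targets 19 rose, Cdkn1a by 4.66 ± 0.423, and Fas fell (camera adjusted p = 4.88e-08; adjusted p = 0.00582 with an estimated correlation). NRF2 targets rose in 9 of 17 genes, Srxn1 by 3.84 ± 0.188, with Gclm and Cat falling (camera adjusted p = 3.5e-05; adjusted p = 0.0136 with an estimated correlation).

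In the same livers 19 of 24 hepatocyte function genes fell, Hal at -3.82 ± 0.214 and Fbp1 at -1.97 ± 0.174 (camera adjusted p = 4.88e-08; adjusted p = 0.0136 with an estimated correlation). Of 14 bile acid genes 8 fell, Cyp7b1 at -4.63 ± 0.317, while Cyp8b1 and Abcb4 rose (camera adjusted p = 0.000456; adjusted p = 0.0482 with an estimated correlation). Xenobiotic metabolism fell in 12 of 19 genes, the nuclear receptor gene Nr1i3 at -2.24 ± 0.194, and Abcc3 rose (camera adjusted p = 0.000433; adjusted p = 0.0392 with an estimated correlation). Endothelial markers fell in 7 of 12 genes, Stab2 at -4.36 ± 0.230 and Kdr at -3.69 ± 0.212 (camera adjusted p = 2.26e-06; adjusted p = 0.00014 with an estimated correlation). Of the clock genes 8 fell, Hlf at -4.41 ± 0.252, and Per1 and Bhlhe40 rose (camera adjusted p = 0.00863; adjusted p = 0.0373 with an estimated correlation). The markers of monocytes and recruited macrophages rose in 7 of 8 genes, Lyz2 by 1.55 ± 0.170 (camera adjusted p = 0.00119; adjusted p = 0.0136 with an estimated correlation). Camera also called the cholesterol and HDL transport list downward (adjusted p = 0.0108), and the cell cycle (adjusted p = 0.0133) and lysosome (adjusted p = 0.00498) lists upward, and these had an adjusted p = 0.124, 0.292 and 0.117 with an estimated correlation. Abcg5 fell by 3.23 ± 0.206 and the lysosomal gene Cd68 rose by 3.26 ± 0.238. For fatty acid oxidation the median was -0.452, the mean 0.0164 and the test direction downward (camera adjusted p = 0.298). In total 6102 genes were changed, 3134 higher and 2968 lower, with 1689 and 1564 at an absolute log2 fold change of at least 1. Scaled by library totals alone the numbers were 4294 higher and 2153 lower, and the median of all genes was 0.268. Replicate 1 of this group stood apart, with chi-squared per degree of freedom of 52.7 to 73.4 against the others, which had 12.5 to 22.3 among themselves. Without it the count was 5472, 2743 higher and 2729 lower.

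With LX-A2003 at 72 h, Scarb1 fell by 5.78 ± 0.263 (adjusted p = 6.18e-22). Sqle rose by 4.76 ± 0.352 (adjusted p = 2.33e-14), followed by 1110028F11Rik at 3.57 ± 0.178 (adjusted p = 2.03e-20) and Cntnap1 at 3.30 ± 0.306 (adjusted p = 2.54e-11). Immp2l, a mitochondrial protease gene of 931.5 kb, fell by 6.65 ± 0.425 (adjusted p = 1.41e-16), with Fhit at -6.55 ± 0.517 (adjusted p = 1.38e-13) and Slc25a21 at -5.20 ± 0.359 (adjusted p = 1.93e-15). Sterol synthesis rose in 18 of 19 genes and in 19 adjusted over the list alone, Cyp51 by 2.32 ± 0.207 (camera adjusted p = 3.52e-29; adjusted p = 0.00042 with an estimated correlation). The interferon response rose in 9 of 22 genes, Cxcl10 by 2.52 ± 0.271 (camera adjusted p = 1.13e-07; adjusted p = 0.00897 with an estimated correlation). Endothelial markers Stab2 (-2.07 ± 0.20), Kdr, Oit3 and Dnase1l3 fell (camera adjusted p = 2.04e-05; adjusted p = 0.000676 with an estimated correlation). Xenobiotic metabolism fell in 9 of 19 genes, Nr1i2 at -1.36 ± 0.163 (camera adjusted p = 3.81e-05; adjusted p = 0.0336 with an estimated correlation). NRF2 targets rose in 7 of 17, Ugdh by 1.15 ± 0.131 (camera adjusted p = 0.00027; adjusted p = 0.0449 with an estimated correlation). Injury genes Krt18, Myc, Jun, Gadd45a and Klf6 rose, and 8 of the list adjusted over the list alone (camera adjusted p = 0.000185; adjusted p = 0.0449 with an estimated correlation). Fatty acid synthesis (7 of 16 genes higher), the p53, ER stress, inflammatory and cell cycle lists were called upward by camera with adjusted p = 2.57e-05, 0.0425, 0.00124, 0.0258 and 0.00452. They had an adjusted p = 0.107, 0.325, 0.162, 0.0513 and 0.301 with an estimated correlation. Adjusted over the list alone, 10, 8, 6, 5 and 4 of their genes rose. In total 1524 genes were changed, 694 higher and 830 lower, with 315 and 395 at an absolute log2 fold change of at least 1. With only the 8 libraries compared the count was 2509. Replicate 1 stood apart, with chi-squared per degree of freedom of 21.2 to 25.8 against the others, which had 6.80 to 9.25 among themselves.

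With LX-A3928 at 72 h, Scarb1 fell by 5.26 ± 0.254 (adjusted p = 1.54e-20). Fgf21 rose by 3.89 ± 0.642 (adjusted p = 2.79e-05) and 1110028F11Rik by 3.34 ± 0.177 (adjusted p = 3.51e-19). Fhit fell by 5.93 ± 0.489 (adjusted p = 9.97e-13), with Immp2l at -5.63 ± 0.386 (adjusted p = 2.87e-15) and Naaladl2 at -5.15 ± 0.422 (adjusted p = 8.82e-13). Sterol synthesis rose in 13 of 19 genes, 15 adjusted over the list alone, Sqle by 3.34 ± 0.361 (camera adjusted p = 7.74e-18; adjusted p = 0.00559 with an estimated correlation). Endothelial markers Stab2 (-2.65 ± 0.206), Kdr, Oit3 and Dnase1l3 fell (camera adjusted p = 1.29e-06; adjusted p = 0.000222 with an estimated correlation). The interferon response rose in 8 of 22 genes, Usp18 by 1.56 ± 0.212 (camera adjusted p = 3.33e-05; adjusted p = 0.0614 with an estimated correlation). Of the clock genes 8 rose and 6 fell, Arntl at -2.77 ± 0.231, and the median was 0.359, the mean 0.0345 and the test direction downward (camera adjusted p = 0.646). Asns rose by 3.57 ± 0.545 among ER stress genes, of which 7 rose adjusted over the list alone (camera adjusted p = 0.00959; adjusted p = 0.275 with an estimated correlation). Among xenobiotic genes Cyp2b10, Cyp2c55, Nr1i2 and Nr1i3 fell, and 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0194; adjusted p = 0.275 with an estimated correlation). Fatty acid synthesis, NRF2 targets, the cell cycle, injury and inflammatory lists were called upward by camera with adjusted p = 0.00423 for the first 3, 0.0155 and 0.0244. They had an adjusted p = 0.285, 0.151, 0.275, 0.275 and 0.0837 with an estimated correlation, and 5, 3, 4, 4 and 2 of their genes rose, with 7 NRF2 targets adjusted over the list alone. In total 1242 genes were changed, 566 higher and 676 lower, with 212 and 327 at an absolute log2 fold change of at least 1. Scaled by library totals alone the numbers were 391 and 750. Replicate 4 of this group stood apart, with chi-squared per degree of freedom of 48.0 to 55.7 against the others, which had 11.8 to 21.0 among themselves, and had 89.8 CPM of the nuclear transcript Neat1 against 922.3 to 1052.

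**Figure D2:**
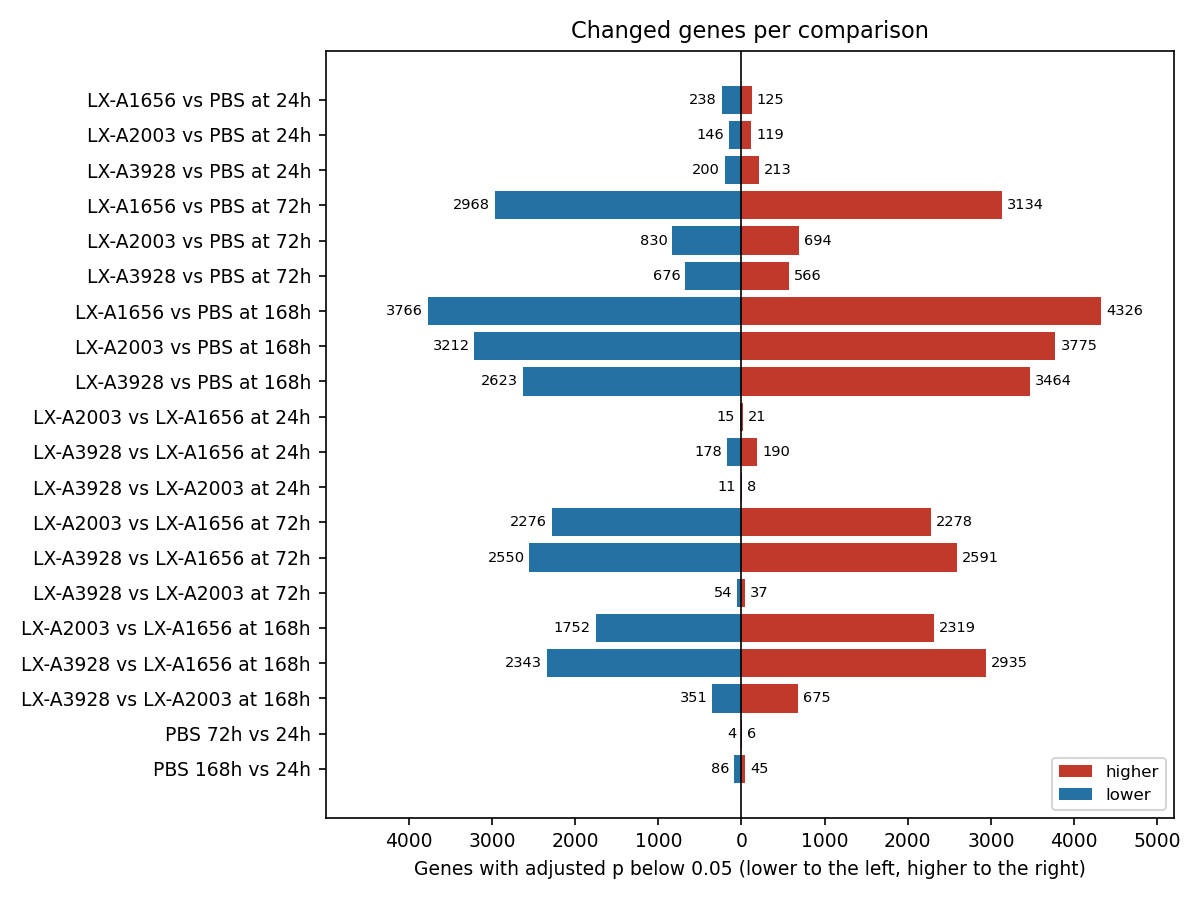
Number of changed genes (adjusted p under 0.05, edgeR) for each oligonucleotide against PBS, each pair of oligonucleotides and PBS over time, with bars to the right for higher and to the left for lower genes and 4 libraries per group. Against PBS the bars reach 3134 higher genes for LX-A1656 at 72 h and 4326 at 168 h, against at most 213 at 24 h.

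In PBS livers at 168 h replicates 1 and 3 stood apart, with chi-squared per degree of freedom of 28.1 to 43.9 against the others and each other, and 6.64 between replicates 2 and 4. At 168 h, the seventh day, Scarb1 fell by 4.30 ± 0.239 with LX-A1656 (adjusted p = 3.81e-20). Asb11 had 0 counts in PBS livers and was at least 561-fold higher, and Krt5 was at least 329-fold higher. Gpnmb, a lysosomal glycoprotein gene of macrophages, had 1 count in PBS livers, with a ratio of treated to PBS between 681 and 150000 (95% counting interval). The steroid dehydrogenase gene Hsd3b5 fell by 10.67 ± 0.630 (adjusted p = 2.42e-18), with the carbonic anhydrase gene Car3 at -10.27 ± 0.282 (adjusted p = 6.29e-31) and the sulfotransferase gene Sult2a8 at -9.01 ± 0.476 (adjusted p = 2.38e-20). Of 17 injury genes 16 rose, the fetal liver gene Afp by 9.88 ± 0.364 and Anxa2 by 5.49 ± 0.252 (camera adjusted p = 6.69e-15; adjusted p = 8.77e-05 with an estimated correlation). The inflammatory list rose in 13 of 15 genes, Ccl2 by 7.34 ± 0.433 (camera adjusted p = 3.74e-07; adjusted p = 8.77e-05 with an estimated correlation), and the interferon response in 17 of 22, Usp18 by 4.05 ± 0.227 (camera adjusted p = 3.39e-05; adjusted p = 0.0361 with an estimated correlation). Bile acid genes fell in 12 of 14, Cyp7b1 at -8.60 ± 0.398, and Abcb4 rose (camera adjusted p = 5.41e-08; adjusted p = 0.00524 with an estimated correlation). Xenobiotic metabolism fell in 12 of 19 genes, Cyp2c29 at -6.36 ± 0.280, while Cyp3a13, Cyp1a1, Por and Abcc2 rose (camera adjusted p = 0.000228; adjusted p = 0.0403 with an estimated correlation). The lysosome list rose in 15 of 20 genes, Cd63 by 4.42 ± 0.212 (camera adjusted p = 3.16e-05; adjusted p = 0.0361 with an estimated correlation). Cell cycle genes rose in 17 of 19 (camera adjusted p = 0.000146; adjusted p = 0.0991 with an estimated correlation), p53 targets in 17 of 25 (camera adjusted p = 0.000235; adjusted p = 0.0513 with an estimated correlation) and sterol synthesis in 16 of 19, Sqle by 5.88 ± 0.349 (camera adjusted p = 0.00673; adjusted p = 0.361 with an estimated correlation). Hepatocyte function genes fell in 15 of 24, Hal at -3.57 ± 0.211, while G6pc, Pck1 and Tat rose (camera adjusted p = 0.0024; adjusted p = 0.203 with an estimated correlation). Fatty acid synthesis fell in 10 of 16 genes, Elovl5 at -2.26 ± 0.172 (camera adjusted p = 0.0312; adjusted p = 0.366 with an estimated correlation).

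Among cell type markers in these livers, those of monocytes and recruited macrophages rose in 7 of 8 genes, Lyz2 by 3.16 ± 0.179 (camera adjusted p = 3.74e-07; adjusted p = 0.000278 with an estimated correlation). Stellate cell and fibroblast markers rose in 11 of 12, Col1a1 by 3.14 ± 0.334 (camera adjusted p = 0.000516; adjusted p = 0.0361 with an estimated correlation). Of the endothelial markers 6 fell, Dnase1l3 at -4.24 ± 0.198, and Lyve1, Pecam1 and Cdh5 rose (camera adjusted p = 0.0168; adjusted p = 0.0375 with an estimated correlation). Kupffer markers rose in 7 of 10 with Timd4 falling, neutrophil markers rose in 7 of 7, and erythroid Alas2 fell by 3.81 ± 0.174, with camera adjusted p = 0.0304, 0.0313 and 0.0281 for the lists. These had an adjusted p = 0.218, 0.154 and 0.131 with an estimated correlation. The lists with a camera adjusted p above 0.05 had members moving both ways or few calls. These were cholesterol and HDL transport (0.582), fatty acid oxidation (0.0941), ER stress (0.73), NRF2 targets (0.449), acute phase (0.966), oligonucleotide uptake and RNase H (0.373), clock (0.708), T cells (0.708), NK cells (0.723), B and plasma cells (0.73), cholangiocytes (0.48), pancreatic acinar cells (0.328) and adipocytes (0.303), each given with its camera adjusted p. The median, mean and test direction differed in sign for cholesterol transport (-0.0681, 0.0886, downward), ER stress (-0.334, 0.517, upward) and the clock (0.198, 0.0944, downward), and the test also differed from the median for pancreatic acinar markers. Among them Lcn2 rose by 8.08 ± 0.464, Atf3 by 4.90 ± 0.260 and Per1 by 6.44 ± 0.546, and Lipc fell by 4.93 ± 0.202. In total 8092 genes were changed, 4326 higher and 3766 lower, with 2931 and 2212 at an absolute log2 fold change of at least 1. Scaled by library totals alone the numbers were 6469 and 2303, and the median of all genes was 0.564. Replicate 4 had a mean small nuclear and nucleolar RNA level of 7.67 log2 CPM, against 6.41 to 6.53 in the others of its group, and chi-squared per degree of freedom of 45.4 to 50.7 against them, where they had 10.6 to 27.4 among themselves.

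With LX-A2003 at 168 h, Scarb1 fell by 4.68 ± 0.245 (adjusted p = 1.49e-20). Krt5 and Fosl1 had 0 PBS counts and were at least 254-fold and 180-fold higher, and for Gpnmb, with 1 PBS count, the ratio lay between 183 and 40400. Immp2l fell by 7.48 ± 0.451 (adjusted p = 2.08e-18), Mup21, a major urinary protein gene, by 6.70 ± 0.480 (adjusted p = 2.33e-15) and Fhit at -6.69 ± 0.491 (adjusted p = 1.29e-15). Cell cycle genes rose in 19 of 19, the cyclin genes Ccnb2 by 3.92 ± 0.270 and Ccnd1 by 4.06 ± 0.286 (camera adjusted p = 5.58e-12; adjusted p = 0.00295 with an estimated correlation). Injury genes rose in 16 of 17, Anxa2 by 5.09 ± 0.248 (camera adjusted p = 2.52e-19; adjusted p = 1.26e-05 with an estimated correlation). Interferon genes rose in 19 of 22, Irf7 by 2.20 ± 0.161 (camera adjusted p = 1.55e-08; adjusted p = 0.00399 with an estimated correlation). Sterol synthesis rose in 17 of 19 genes, Sqle by 6.59 ± 0.353, and Sc5d and Stard4 fell (camera adjusted p = 2.76e-08; adjusted p = 0.0361 with an estimated correlation). Hepatocyte function genes fell in 18 of 24, Hal at -3.83 ± 0.214 (camera adjusted p = 4.56e-07; adjusted p = 0.025 with an estimated correlation), and bile acid genes in 12 of 14, Cyp7b1 at -5.60 ± 0.333 (camera adjusted p = 2.11e-06; adjusted p = 0.0144 with an estimated correlation). The p53, NRF2, inflammatory, lysosome, monocyte and stellate lists were called upward and xenobiotic metabolism downward, by camera and with an estimated correlation. Kupffer markers rose in 6 of 10 (camera adjusted p = 0.0144; adjusted p = 0.145 with an estimated correlation). In total 6987 genes were changed, 3775 higher and 3212 lower, with 2579 and 1500 at an absolute log2 fold change of at least 1. Scaled by library totals alone the numbers were 5865 and 1685, and the median of all genes was 0.451. Replicate 4 had chi-squared per degree of freedom of 36.7 to 85.5 against the others, which had 13.1 to 22.0 among themselves, and without it the count was 7184.

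With LX-A3928 at 168 h, Scarb1 fell by 5.09 ± 0.251 (adjusted p = 3.17e-21). Krt5 was at least 113-fold higher over 0 PBS counts. Spink1, a trypsin inhibitor gene, rose by 8.34 ± 0.589 (adjusted p = 1.19e-15), over few PBS counts, so the size of this fold is uncertain. Immp2l fell by 7.69 ± 0.465 (adjusted p = 4.2e-18), with the vaspin gene Serpina12 at -6.51 ± 0.765 (adjusted p = 2.14e-09). Cell cycle genes rose in 19 of 19, Ccna2 by 4.04 ± 0.322 (camera adjusted p = 2.04e-14; adjusted p = 0.000655 with an estimated correlation). Injury genes rose in 16 of 17, Tnfrsf12a by 4.38 ± 0.237 (camera adjusted p = 7.68e-18; adjusted p = 2.97e-05 with an estimated correlation), and interferon genes in 19 of 22, Usp18 by 3.19 ± 0.223 (camera adjusted p = 4.43e-13; adjusted p = 0.000277 with an estimated correlation). Hepatocyte function genes fell in 18 of 24, Hal at -3.39 ± 0.210 (camera adjusted p = 2.72e-08; adjusted p = 0.0201 with an estimated correlation), and xenobiotic genes in 12 of 19, Cyp2c29 at -4.05 ± 0.250 (camera adjusted p = 2.89e-05; adjusted p = 0.0212 with an estimated correlation). Sterol synthesis rose in 14 of 19, Sqle by 5.76 ± 0.348, with Sc5d and Stard4 falling (camera adjusted p = 2.89e-05; adjusted p = 0.149 with an estimated correlation). The p53, NRF2, inflammatory, lysosome, monocyte and stellate lists were called upward and bile acid genes downward, by camera and with an estimated correlation. In total 6087 genes were changed, 3464 higher and 2623 lower, with 2254 and 1075 at an absolute log2 fold change of at least 1. Scaled by library totals alone the numbers were 5144 and 1458, and the median of all genes was 0.386. Replicate 3 of this group stood apart from the others, with chi-squared per degree of freedom of 133.5, 219.8 and 217.1 against replicates 1, 2 and 4, which had 14.4 to 84.7 among themselves. Its 10 most abundant genes took 18.2% of counts, against 10.5% to 11.9%, and its mean small nuclear and nucleolar RNA level was 9.19 log2 CPM, against 5.84 to 7.60. Without it the count was 6295, 3376 higher and 2919 lower, and with only the 8 libraries compared it was 3208.

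**Figure D3:**
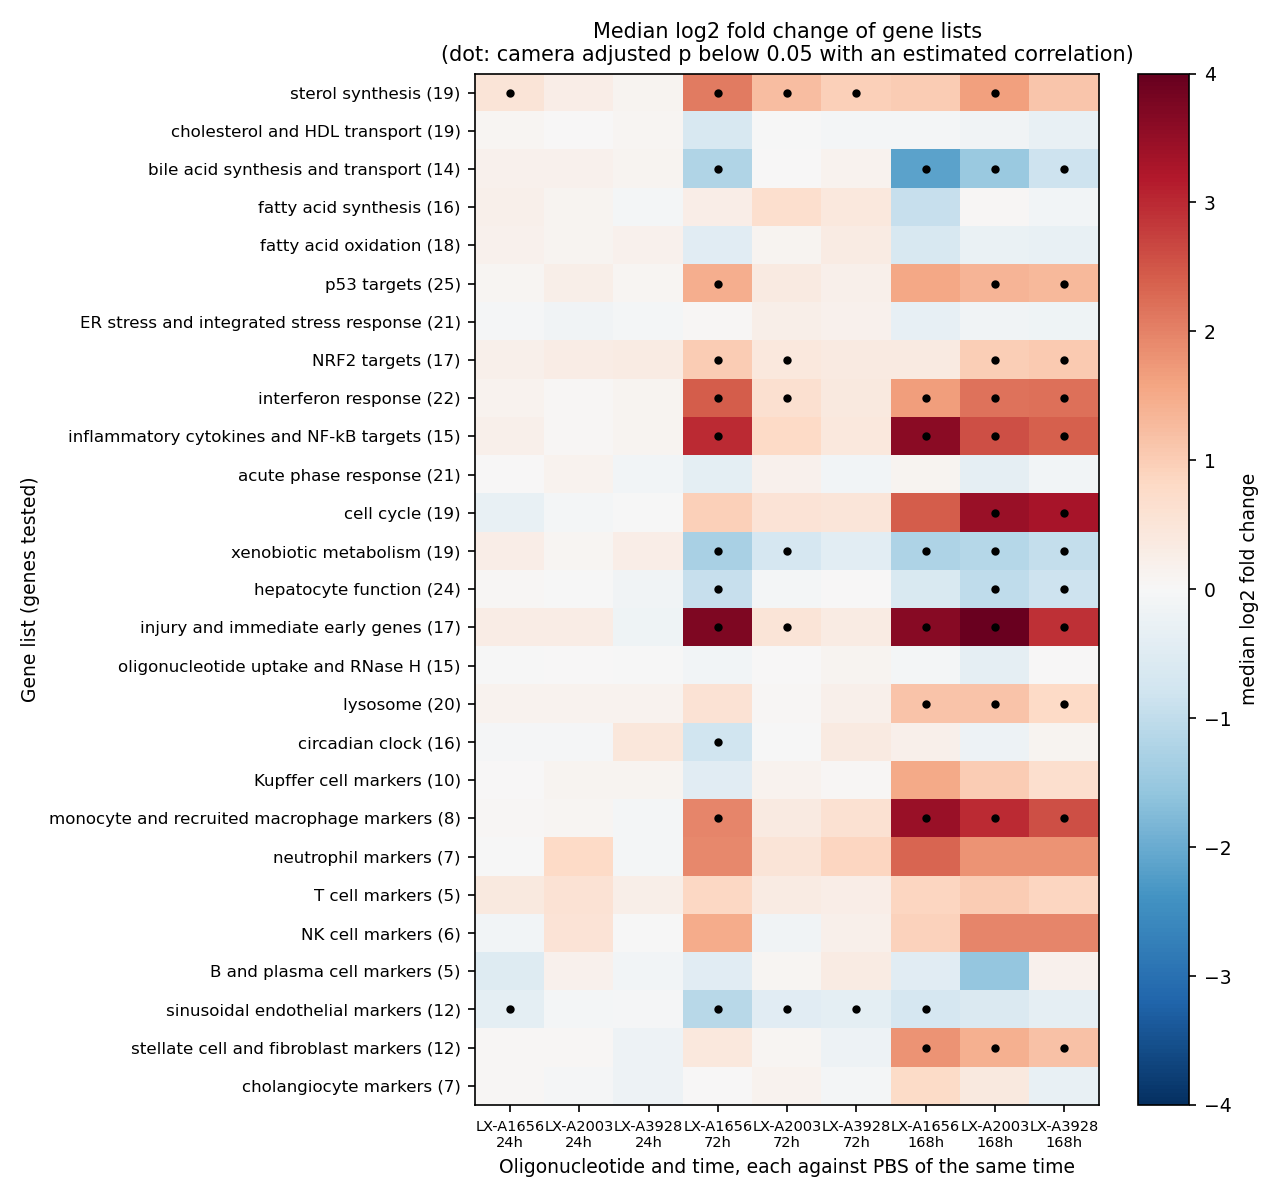
Median log2 fold change against PBS of each gene list with at least 5 tested genes (vertical axis) for each oligonucleotide and time in h (horizontal axis), as colour, with a dot where camera with an estimated correlation gave an adjusted p under 0.05. No list has a dot for LX-A2003 or LX-A3928 at 24 h. At 168 h the injury list has a dot in all 3 oligonucleotide groups and the cell cycle list with LX-A2003 and LX-A3928.

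The oligonucleotides, which share their target, were then compared at matched times. At 24 h Scarb1 was higher with LX-A2003 than with LX-A1656 by 1.12 ± 0.229 (adjusted p = 0.0103), higher with LX-A3928 than with LX-A1656 by 2.18 ± 0.230 (adjusted p = 1.55e-08) and higher with LX-A3928 than with LX-A2003 by 1.06 ± 0.216 (adjusted p = 0.0145). Kdr was higher with LX-A2003 than with LX-A1656 by 1.82 ± 0.202 (adjusted p = 1.48e-07) and Stab2 by 1.21 ± 0.201, and 5 of 12 endothelial markers were higher when adjusted over the list alone (camera adjusted p = 4.35e-13; adjusted p = 1.59e-07 with an estimated correlation). Between LX-A3928 and LX-A1656, Dbp was higher by 3.06 ± 0.481 (adjusted p = 9.42e-05) and Sox5 by 2.75 ± 0.301 (adjusted p = 2.53e-08), and Nr0b2 fell by 2.74 ± 0.375 (adjusted p = 9.11e-06). The endothelial markers Kdr, Stab2 and Oit3 were higher there, and 6 adjusted over the list alone (camera adjusted p = 2.31e-08; adjusted p = 1.64e-05 with an estimated correlation). Camera called the sterol synthesis list downward relative to LX-A1656 for LX-A2003 (adjusted p = 1.3e-05; adjusted p = 0.232 with an estimated correlation), where no single gene passed and 1 was lower adjusted over the list alone. It did so too for LX-A3928 (adjusted p = 1.79e-07; adjusted p = 0.179 with an estimated correlation), where Pmvk was called lower and 9 genes were lower adjusted over the list alone. Between LX-A3928 and LX-A2003, Myc was higher by 2.19 ± 0.433 (adjusted p = 0.0113), and Nr0b2 was lower at -2.26 ± 0.370 (adjusted p = 0.000895) and Npas2 at -2.13 ± 0.339 (adjusted p = 0.000754). The clock list had a camera adjusted p = 0.0117 (adjusted p = 0.111 with an estimated correlation).

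In these comparisons at 24 h, 36 genes were changed for LX-A2003 against LX-A1656, 21 higher and 15 lower. The count was 11 without LX-A1656 replicate 1, 11 without its replicate 2, 14 without LX-A2003 replicate 1 and 11 without its replicate 2. LX-A3928 against LX-A1656 gave 368 genes, 190 higher and 178 lower. The count was 192, 196 and 194 without LX-A1656 replicate 1, 2 or 3, and 239, 238 and 159 without LX-A3928 replicate 1, 2 or 3. Without LX-A1656 replicate 4 it was 462, with a majority of lower genes. LX-A3928 against LX-A2003 gave 19 genes, 8 higher and 11 lower, with 53.57% of the calls higher in DESeq2. The count was 6, 9 and 12 without LX-A2003 replicate 1, 3 or 4, and 10, 7 and 9 without LX-A3928 replicate 2, 3 or 4. Without LX-A2003 replicate 2 the majority turned, with 14 higher and 10 lower. With only the 8 libraries compared the counts were 154, 1455 and 77. In these 3 comparisons camera called 9, 3 and 3 of the 30 lists, and 1, 1 and 0 with an estimated correlation.

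At 72 h Scarb1 with LX-A2003 differed from LX-A1656 by 0.32 (95% interval -0.175 to 0.815, adjusted p = 0.346) and with LX-A3928 from LX-A2003 by 0.52 (interval 0.0396 to 0.994 before adjustment, adjusted p = 0.539), and it was higher with LX-A3928 than with LX-A1656 by 0.84 ± 0.246 (adjusted p = 0.00539). The bile acid enzyme gene Cyp7b1 was higher than with LX-A1656 by 4.07 ± 0.309 in LX-A2003 livers (adjusted p = 3.31e-14) and by 4.36 ± 0.313 in LX-A3928 livers (adjusted p = 3.54e-15). Krt5, at 0 counts in LX-A2003 and in LX-A3928 livers, was at least 318-fold and 311-fold lower than with LX-A1656. Injury genes were lower than with LX-A1656 in 15 of 17 with LX-A2003 (camera adjusted p = 1.7e-27; adjusted p = 2.68e-07 with an estimated correlation) and 15 of 17 with LX-A3928 (camera adjusted p = 3.58e-26; adjusted p = 8.84e-07 with an estimated correlation). Interferon genes were lower in 19 of 22 (camera adjusted p = 1.31e-19; adjusted p = 1.37e-05 with an estimated correlation) and in 20 of 22 (camera adjusted p = 1.43e-19; adjusted p = 1.29e-05 with an estimated correlation). Hepatocyte function genes were higher in 19 of 24 (camera adjusted p = 1.86e-12; adjusted p = 0.0022 with an estimated correlation) and in 18 of 24, or 20 adjusted over the list alone (camera adjusted p = 8.23e-11; adjusted p = 0.00475 with an estimated correlation). Against LX-A1656, LX-A2003 gave 4554 changed genes, 2278 higher and 2276 lower, and LX-A3928 gave 5141, 2591 higher and 2550 lower. Library totals alone gave 1421 higher and 3650 lower, and 1495 and 4257, with medians of all genes of -0.259 and -0.317.

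LX-A3928 against LX-A2003 at 72 h gave 91 changed genes, 37 higher and 54 lower, and 18 and 57 with library totals alone. Usp2 was higher by 2.48 ± 0.300 (adjusted p = 5.88e-07) and Arntl lower at -2.32 ± 0.229 (adjusted p = 4.25e-09). In sterol synthesis Hmgcs1, Sqle, Cyp51 and Nsdhl were lower and 1 gene was higher, with 8 lower adjusted over the list alone (camera adjusted p = 2.06e-08; adjusted p = 0.199 with an estimated correlation). The count was 50 and 56 without LX-A2003 replicate 3 or 4, and 55 and 49 without LX-A3928 replicate 1 or 3. At 72 h camera called 16 of the 30 lists for LX-A2003 and 15 for LX-A3928 against LX-A1656, and 6 between LX-A3928 and LX-A2003. With an estimated correlation it called 9, 10 and 0.

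At 168 h Scarb1 with LX-A2003 differed from LX-A1656 by -0.38 (95% interval -0.816 to 0.0501, adjusted p = 0.185) and with LX-A3928 from LX-A2003 by -0.41 (interval -0.855 to 0.0356, adjusted p = 0.282), and it was lower with LX-A3928 than with LX-A1656 at -0.79 ± 0.225 (adjusted p = 0.00392). The organic anion transporter gene Slco1a1 was higher than with LX-A1656 by 5.03 ± 0.435 with LX-A2003 (adjusted p = 4.13e-12) and by 7.43 ± 0.466 with LX-A3928 (adjusted p = 1.71e-16). Hsd3b5 was higher with LX-A3928 than with LX-A1656 by 7.68 ± 0.595 (adjusted p = 1.01e-13) and than with LX-A2003 by 3.34 ± 0.431 (adjusted p = 1.9e-06). The mast cell tryptase gene Tpsab1 was lower with LX-A3928 than with LX-A1656 at -7.48 ± 0.530 (adjusted p = 4.08e-15). Bile acid genes were higher than with LX-A1656 in 9 of 14 with LX-A2003 (camera adjusted p = 6.57e-06; adjusted p = 0.0486 with an estimated correlation) and in 12 of 14 with LX-A3928 (camera adjusted p = 4e-08; adjusted p = 0.0148 with an estimated correlation). Between LX-A3928 and LX-A2003 the injury genes Fos, Egr1, Ier3, Gadd45b and Afp were lower, with 10 lower adjusted over the list alone (camera adjusted p = 4.05e-07; adjusted p = 0.0193 with an estimated correlation). LX-A2003 against LX-A1656 gave 4071 changed genes, 2319 higher and 1752 lower. LX-A3928 against LX-A1656 gave 5278, 2935 higher and 2343 lower, with 2095 and 3057 by library totals alone and 2870 with only the 8 libraries compared.

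LX-A3928 against LX-A2003 at 168 h gave 1026 changed genes, 675 higher and 351 lower, and 309 and 418 with library totals alone, which moved the median of all genes to -0.110. Sult2a8 was higher by 3.31 ± 0.359 (adjusted p = 1.31e-07) and the intestinal keratin gene Krt20 was lower at -3.21 ± 0.391 (adjusted p = 1.9e-06). The count depended on single libraries. It was 506, 527, 604 and 1637 without LX-A2003 replicate 1, 2, 3 or 4, and 1801 and 1807 without LX-A3928 replicate 2 or 4. Without LX-A3928 replicate 3 it was 230, with 85 higher and 145 lower, and with only the 8 libraries compared it was 29, with 4 higher and 25 lower, so the majority turned in both. At 168 h camera called 10 of the 30 lists for LX-A2003 and 9 for LX-A3928 against LX-A1656, and 9 between LX-A3928 and LX-A2003. With an estimated correlation it called 3, 3 and 1.

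Whether the effect against PBS differed between 168 h and 24 h was tested as an interaction. For Scarb1 the difference was 0.39 ± 0.307 with LX-A1656 (adjusted p = 0.312), -1.12 ± 0.303 with LX-A2003 (adjusted p = 0.00285) and -2.59 ± 0.306 with LX-A3928 (adjusted p = 6.4e-09). With LX-A1656 Car3 had a fold change of -0.0232 at 24 h and -10.27 at 168 h, a difference of -10.25 ± 0.320 (adjusted p = 1.66e-28), and Hsd3b5 a difference of -10.5 ± 0.721 (adjusted p = 1.21e-15). With LX-A2003 Mup21 differed by -6.70 ± 0.582 (adjusted p = 2.93e-12), and with LX-A3928 Immp2l by -6.19 ± 0.582 (adjusted p = 1.75e-11) and Serpina12 by -6.44 ± 0.930 (adjusted p = 6.06e-07). The injury list had a larger fold change at 168 h in 16 of 17 genes with LX-A1656 (camera adjusted p = 1.5e-14; adjusted p = 0.000191 with an estimated correlation), 16 with LX-A2003 (camera adjusted p = 1.76e-18; adjusted p = 1.58e-05 with an estimated correlation) and 13 with LX-A3928 (camera adjusted p = 1.33e-16; adjusted p = 4.62e-05 with an estimated correlation). For the cell cycle the numbers were 15, 17 and 18 of 19 genes (camera adjusted p = 1.79e-05, 1.01e-12 and 2.23e-14; adjusted p = 0.0634, 0.00259 and 0.00117 with an estimated correlation). Of the 30 lists camera called 15 for each oligonucleotide, and 8, 10 and 9 with an estimated correlation. Changed genes numbered 5955 with LX-A1656 (2936 higher, 3019 lower), 4878 with LX-A2003 (2536 and 2342) and 4106 with LX-A3928 (2199 and 1907). Library totals alone gave 4935 and 1676, 4414 and 1130, and 3609 and 992, with medians of all genes of 0.560, 0.488 and 0.406.

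Vehicle livers were compared over time as the background to these changes. Scarb1 differed by 0.16 ± 0.207 between 72 h and 24 h (adjusted p = 1) and by 0.24 ± 0.207 between 168 h and 24 h (adjusted p = 0.601). At 72 h Dbp was higher than at 24 h by 3.85 ± 0.595 (adjusted p = 0.000604) and Angptl4 by 1.44 ± 0.281 (adjusted p = 0.0147), and Ppard was lower at -1.70 ± 0.247 (adjusted p = 0.000209). At 168 h Foxq1 was higher than at 24 h by 2.28 ± 0.477 (adjusted p = 0.00754), and the bile acid enzyme gene Cyp7a1 was lower at -2.59 ± 0.609 (adjusted p = 0.0249) and Clic3 at -1.96 ± 0.278 (adjusted p = 3.81e-05). Camera called fatty acid oxidation upward at 72 h (adjusted p = 0.000109; adjusted p = 0.311 with an estimated correlation). It called the ER stress list downward at 168 h, with Hspa5, Dnajb9 and Creld2 lower, 7 lower adjusted over the list alone, and Chac1 higher (adjusted p = 0.000167; adjusted p = 0.408 with an estimated correlation). It called 4 of the 30 lists at 72 h and 3 at 168 h, and with an estimated correlation no list at either time. At 72 h 10 genes were changed, 6 higher and 4 lower, with 72.7% of 33 calls higher in DESeq2. The count was 2, 4 and 5 without PBS replicate 1, 2 or 4 at 24 h, and 3, 3 and 33 without PBS replicate 1, 3 or 4 at 72 h. Of the 5 without PBS replicate 4 at 24 h, 2 were higher and 3 lower. At 168 h 131 genes were changed, 45 higher and 86 lower, with 23 and 99 by library totals alone and 44.2% of 274 calls higher in DESeq2. The count was 47, 58 and 71 without PBS replicate 1, 2 or 4 at 24 h, and 65 without PBS replicate 1 at 168 h.

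Fold changes of different oligonucleotides were compared across genes, which are not independent replicates, at each time. At 24 h the covariance was 0.146 for LX-A1656 and LX-A2003, against 0.0731 in simulations where only the shared PBS libraries link the groups and 0.0792 with the PBS libraries split. It was 0.138 for LX-A1656 and LX-A3928 (simulated 0.0738, split 0.0694) and 0.167 for LX-A2003 and LX-A3928 (simulated 0.0758, split 0.103). The simulated values are a reference for the covariance with shared PBS libraries only. With the PBS libraries split the comparisons share no library, so the split values hold no part that comes from sharing. Genes called lower with both numbered 72, 65 and 85, where independent calls would give 2.74, 3.76 and 2.30, and with the PBS libraries split 23 to 33, 18 to 26 and 25 to 31. At 168 h the covariances were 2.49, 2.01 and 1.86 (simulated 0.0855, 0.0851 and 0.0836, split 2.52, 2.02 and 1.86), and genes called higher with both numbered 3150, 2749 and 2952, against 1289, 1183 and 1032 for independent calls. At 72 h LX-A1656 and LX-A2003 had 546 genes higher with both against 171.6 for independent calls, and 28 genes called in opposite directions. With the PBS libraries split, 242 to 286 genes were higher with both. Across genes, without shared libraries, the 168 h fold changes of LX-A3928 had a correlation of 0.794 with the 72 h fold changes of LX-A1656 and 0.461 with those of LX-A3928 itself. This was not particular to LX-A3928. Among the 72 h profiles, that of LX-A1656 also had the highest correlation with the 168 h fold changes of LX-A1656, 0.716, and of LX-A2003, 0.779.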

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

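The clock tests, the small RNA tests and the counts of other splits of the libraries were chosen only after the results they measure had been seen.

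Among 8 measures in 88 groups of 4 libraries with any spread, 6 groups held a library far from the rest by Dixon's ratio, and chance alone marks about 1 in 20 groups. LX-A1656 replicate 4 at 24 h had 14560 genes detected, against 14060 to 14140 in the others. The mean small nuclear and nucleolar RNA level was 6.69 log2 CPM in LX-A3928 replicate 2 at 24 h (others 6.33 to 6.37), 6.69 in LX-A2003 replicate 1 at 72 h (others 6.45 to 6.49) and 7.67 in LX-A1656 replicate 4 at 168 h (others 6.41 to 6.53). LX-A3928 replicate 4 at 72 h had 89.8 CPM of Neat1 (others 922.3 to 1052) and 67.1 CPM of Dbp (others 99.9 to 103). LX-A3928 replicate 3 at 168 h, at 9.19 log2 CPM of small RNA (others 5.84 to 7.60), did not reach the limit of Dixon's ratio in that wide group.

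Libraries with more small RNA counts than the rest of their group were weighed against 3 explanations, with 3 relations over 48 libraries tested by 100000 permutations within groups. A link to library size (within-group Pearson r = -0.211, permutation p = 0.24, adjusted p = 0.24) and a link to more dividing cells, read from the cell cycle list (r = 0.181, p = 0.22, adjusted p = 0.24; 0.313 without the 2 farthest libraries), both stay open, since neither passed and neither was excluded. The level of the nuclear transcript Neat1 varied inversely with small RNA (r = -0.697, p = 5e-05, adjusted p = 0.00015; Spearman rho = -0.702, p = 0.00011, adjusted p = 0.00033; r = -0.716 without the 2 farthest libraries). Loss of nuclear RNA at extraction would lower both together, so the inverse relation does not speak for it, and a single transcript does not exclude it. It stays open. Dividing cells were the only biological explanation tested, and the design names no other within a group.

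The effect against PBS differed between 168 h and 24 h for 5955 genes with LX-A1656, 4878 with LX-A2003 and 4106 with LX-A3928, by the edgeR test of the interaction. Among the named genes with a lower effect at 168 h were Car3 (-10.25) and Hsd3b5 (-10.5) with LX-A1656, Scarb1 (-1.12) and Mup21 (-6.70) with LX-A2003, and Scarb1 (-2.59), Immp2l (-6.19) and Serpina12 (-6.44) with LX-A3928. The highest differences were those of Fosl1, Gpnmb and Gprc5a with LX-A1656, Fosl1, Spink1 and Ypel4 with LX-A2003, and Ypel4, Gpnmb and Spink1 with LX-A3928. These had at most 6 counts in PBS livers at 168 h, so no fitted difference is given. Other assignments of the times to the treated libraries, with the PBS labels kept, gave at most 17, 82 and 3 genes in the fits of 16 libraries. The real assignments gave 6013, 4813 and 3047, each the only 1 of 35 that large. That is a share of 0.0286, the smallest possible and not adjusted over the comparisons. Since only treated libraries were reassigned, the counts show that these differ between the times. They do not test the difference from PBS apart from that.

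Clock genes in LX-A3928 livers at 24 h were a second pattern, with 9 of 16 called against PBS. Of the 8 called between LX-A3928 and LX-A1656 at 24 h, 7 had the sign of the difference between PBS livers at 72 h and 24 h. Nothing in the labels ties that PBS difference to hours of collection, so different hours of tissue collection stay open. An effect of LX-A3928 on the clock would keep its direction, and all 9 genes called against PBS at 24 h had the same sign at 168 h and at 72 h. The signs at 24 h and 168 h were not particular to LX-A3928. With LX-A1656 and LX-A2003, against the same PBS libraries, all 9 had them at 24 h (Dbp 2.94 and 4.13). At 168 h only Nr1d2 with LX-A2003, at -0.0299, did not. An effect of LX-A3928 also stays open, since hours of collection are not given and could differ between groups at every time.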

How the results depend on the processing

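The alternatives with library totals alone, without libraries far from their group, without 2 PBS libraries at 168 h, and with the small RNA covariate were chosen only after the data had been seen. For each oligonucleotide against PBS, Scarb1 kept its direction and its call under every alternative run, from -6.31 to -5.88 with LX-A1656 at 72 h, where it was lowest, to -2.59 to -2.41 with LX-A3928 at 24 h. Counts of changed genes stayed within 1.5 times the reported count in 23 of 23 comparisons with RLE factors and with library totals alone, in 21 of 23 with the replicate block and the small RNA covariate, in 20 of 23 without the low-count filter, in 18 of 23 with DESeq2, in 13 of 15 without far libraries, in 6 of 7 without 2 PBS libraries at 168 h, and in 10 of 20 with only the 8 libraries.

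With only the 8 libraries compared, and so another estimate of the spread, the counts were 803, 754 and 1435 for LX-A1656, LX-A2003 and LX-A3928 against PBS at 24 h, 2509 for LX-A2003 at 72 h and 3208 for LX-A3928 at 168 h. They were 154, 1455 and 77 between the oligonucleotides at 24 h (LX-A2003 against LX-A1656, LX-A3928 against LX-A1656, LX-A3928 against LX-A2003), and at 168 h 2870 for LX-A3928 against LX-A1656 and 29 against LX-A2003, of which 4 were higher and 25 lower where the reported calls were 675 and 351. DESeq2 gave 404 for LX-A2003 against PBS and 89 for LX-A2003 against LX-A1656 at 24 h, 137 for LX-A3928 against LX-A2003 at 72 h, and 33 and 274 for PBS at 72 h and 168 h. Without the low-count filter the counts were 22 and 229 for LX-A2003 and LX-A3928 against LX-A1656 at 24 h and 73 for PBS at 168 h, with more genes to adjust over. The replicate block gave 18 for LX-A2003 against LX-A1656 at 24 h and 583 for LX-A3928 against LX-A2003 at 168 h, though replicate numbers did not pair the libraries, with 0, 6 and 5 of 24 same-number pairs above a correlation of 0.1 at 24 h, 72 h and 168 h. The block of 6 sets gave 45 for PBS at 168 h, and the small RNA covariate 89 for LX-A2003 against LX-A1656 at 24 h and 20 for PBS at 72 h. Without the far libraries the counts were 264 for LX-A3928 against LX-A2003 at 72 h (133 higher, 131 lower) and 258 for PBS at 168 h, and without PBS replicates 1 and 3 at 168 h the latter was 60. Apart from the filter and the number of libraries, the cause was not tested.

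Leaving out 1 library gave 239 to 314, 135 to 214 and 248 to 332 changed genes against PBS at 24 h for LX-A1656, LX-A2003 and LX-A3928, 5472 to 5977, 1169 to 1344 and 914 to 1238 at 72 h, and 7760 to 7907, 6479 to 7184 and 5638 to 6295 at 168 h. Between LX-A2003 and LX-A1656 the ranges were 11 to 39, 3854 to 4535 and 3362 to 4596 at the 3 times. LX-A3928 against LX-A1656 had 159 to 462, 4420 to 5061 and 4683 to 5282, and against LX-A2003 6 to 24, 49 to 133 and 230 to 1807. The interactions had 5589 to 5847, 4485 to 5083 and 3686 to 4473, and PBS 2 to 33 at 72 h and 47 to 129 at 168 h. The libraries behind moves of over 1.5 times are named with the comparisons.

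Of 15393 values of the named genes under all settings, 14742 kept direction and call, 517 lost the call, 130 gained it and 4 changed sign. These were Saa2 for LX-A2003 against PBS at 24 h (-0.267 without LX-A2003 replicate 2, against up to 1.78 without another library), Cd2 for LX-A1656 at 72 h (-0.0374 without PBS replicate 3, against up to 0.663), neither of them called, Cd79b (0.0286 with library totals alone) and Scarb1 between PBS at 168 h and 24 h (-0.0991 without PBS replicates 1 and 3). For the lists, camera made 89 calls for the oligonucleotides against PBS, 56 with an estimated correlation, and fry, which has another question, 143. With the PBS libraries split, so that the comparisons shared no library, the covariances of fold changes were 0.0792, 0.0694 and 0.103 at 24 h and 0.583, 0.453 and 0.280 at 72 h. By simulation at this depth a 1.5-fold change was called in 15.2% of genes and a 2-fold change in 56.7%.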

Other observations

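The tests of gene span, endothelial markers and the counts of other splits of the libraries were chosen only after the results had been seen.

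Sinusoidal endothelial markers differed in how they moved at 24 h. With LX-A1656 the values were -2.78 ± 0.204 for Kdr and -2.21 ± 0.203 for Stab2, against -0.00116 ± 0.163 for Cdh5 and -0.0934 ± 0.139 for Pecam1, neither of which was called. Span did not separate them, with 45.6 kb for Kdr, 166.8 kb for Stab2 and 18.8 kb for Oit3, which were called, against 42.9 kb for Cdh5, 96.4 kb for Pecam1 and 135.7 kb for Tek, which were not. PBS livers expressed all 12 markers at a mean of at least 1 CPM.

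Genes with long genomic spans were lower in oligonucleotide groups. For 555 genes of at least 200 kb, of 12379 with a known span, the median log2 fold change at 24 h was -0.358 with LX-A1656, -0.170 with LX-A2003 and -0.132 with LX-A3928. At 72 h the medians were -1.10, -0.674 and -0.625, and at 168 h -0.833, -0.522 and -0.508. Of these genes 88, 32 and 26 were called lower at 24 h, with at most 5 higher in each group, 354, 242 and 211 lower and 29, 4 and 5 higher at 72 h, and 300, 262 and 256 lower and 107, 115 and 77 higher at 168 h. The genes called lower at 24 h had a median span of 133.4 kb with LX-A1656, 46.4 kb with LX-A2003 and 30.2 kb with LX-A3928, against 24.3 kb for the genes tested. Those called higher had 18.0, 20.3 and 24.4 kb. Mean CPM of the nuclear transcript Neat1 at 24 h was 324.5 in PBS and 1189, 873.9 and 797.6 with LX-A1656, LX-A2003 and LX-A3928. At 72 h it was 529.1 against 975.9, 1564 and 747.9. None of these differences was called (lowest adjusted p = 0.0712), and a link to the pattern was not tested. At 24 h the lowest oligonucleotide library (527.4) still lay above the highest PBS library (360.4). At 72 h LX-A1656 and LX-A3928 overlapped with PBS. At 168 h the means were 416.5 against 493.8, 435.9 and 291.2, with long genes still lower.

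The SEs of medians, differences and slopes here and below come from resampling genes. They measure the spread between genes and not between libraries, so what is argued against is so for that spread alone. At 24 h the tables argue against low expression of long genes as the whole cause with LX-A1656 and LX-A2003. Long genes lay -0.406 ± 0.0305 and -0.211 ± 0.0199 from matched short genes there. With LX-A3928 the difference was -0.142 ± 0.0253. Between PBS livers at 168 h and 24 h it was -0.112 ± 0.0285, so low expression stays open with LX-A3928. For LX-A1656 the slope on log10 span, -0.172 ± 0.00966, stayed at -0.169 ± 0.0132 with exonic length in the regression. With LX-A2003 it went from -0.0834 ± 0.00860 to -0.0380 ± 0.0119, with a slope on exonic length of -0.120 ± 0.0214, and with LX-A3928 from -0.0444 ± 0.00909 to -0.0186 ± 0.0125, with -0.0682 ± 0.0214 on exonic length. Between PBS groups the slope on span with exonic length was 0.0449 ± 0.00995 at 72 h and 0.00433 ± 0.0111 at 168 h against 24 h. The size of the first, though of opposite sign, is no smaller than that with LX-A2003. Loss of long mature transcripts by degradation stays open for each oligonucleotide. These regressions cannot decide on it, since each value reads an amplified fragment, so a loss by degradation need not follow exonic length. A trend between libraries of different times without treatment is argued against at 24 h for LX-A1656 alone, with slopes of 0.0165 ± 0.00736 for PBS at 72 h and -0.0773 ± 0.00830 for PBS at 168 h against 24 h. The latter is within the spread of the slope with LX-A2003 and steeper than that with LX-A3928.

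At 72 h and 168 h the tables argue against low expression of long genes and a trend without treatment as the whole cause for each oligonucleotide. The slopes on span stayed below those between PBS groups with exonic length in the regression, which leaves degradation open as at 24 h. For LX-A1656, LX-A2003 and LX-A3928 long genes lay -1.37 ± 0.0830, -0.770 ± 0.0407 and -0.737 ± 0.0453 from matched short genes at 72 h, and -1.16 ± 0.101, -0.665 ± 0.0833 and -0.773 ± 0.0889 at 168 h. The slopes on span were -0.596 ± 0.0238, -0.332 ± 0.0139 and -0.281 ± 0.0131 at 72 h, and -0.497 ± 0.0299, -0.335 ± 0.0250 and -0.326 ± 0.0219 at 168 h. With exonic length they were -0.671 ± 0.0329, -0.352 ± 0.0205 and -0.284 ± 0.0189 at 72 h, and -0.656 ± 0.0427, -0.426 ± 0.0364 and -0.339 ± 0.0327 at 168 h.

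Fewer endothelial cells are argued against as the whole cause for LX-A2003 at 72 h, where 10 endothelial markers under 100 kb had a median of -0.338 ± 0.149 against -0.674 ± 0.0336 for long genes. Elsewhere they stay open, with marker medians within 2 SE of those of long genes. The markers' medians at 24 h for LX-A1656, LX-A2003 and LX-A3928 were -0.292 ± 0.187, -0.00430 ± 0.122 and -0.0287 ± 0.0774. At 72 h they were -0.779 ± 0.544 with LX-A1656 and -0.358 ± 0.199 with LX-A3928, and at 168 h -0.341 ± 0.763, -0.0962 ± 0.527 and -0.274 ± 0.594. That oligonucleotide treatment lowers transcripts in proportion to precursor length also stays open, since the slopes, of which -0.0444 was nearest to 0, only restate the pattern.

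The libraries of every comparison of 4 against 4 were also split in all 35 ways, with a fit of only those libraries. Against PBS the real split gave 803, 754 and 1435 changed genes at 24 h for LX-A1656, LX-A2003 and LX-A3928, with at most 1 in any other split. At 72 h it gave 6000, 2509 and 1352, with at most 0, 1 and 4, and at 168 h 7257, 5594 and 3208, with at most 0 in any other split for all 3 (edgeR; for the splits, counts before adjustment were not written). For LX-A2003 against LX-A1656 the real and highest other counts were 154 and 2 at 24 h, 4565 and 0 at 72 h, and 3345 and 862 at 168 h. For LX-A3928 against LX-A1656 they were 1455 and 1, 4460 and 0, and 2870 and 4, and for LX-A3928 against LX-A2003 they were 77 and 21, 68 and 1, and 29 and 1. PBS at 168 h against 24 h gave 126 and 1. In each of these the real split alone was as large, a share of 0.0286, the smallest 35 splits allow, not adjusted over the comparisons. It tests chance labels of libraries, not chance between animals. PBS at 72 h against 24 h gave 11 genes and 2 of 35 splits as many, so chance cannot be excluded. The other was replicates 1, 2 and 4 of PBS at 24 h with replicate 4 of PBS at 72 h against the rest, which called 351 genes. Whether these samples have a structure other than time was not tested, since this split was picked as the highest of 35. A block of 6 sets by library number gave 11 genes between the times and a replicate block 8.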
